A study of Zea mays with 28 samples.

How the data were processed

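Total RNA of Gaspe Flint maize, a dwarf cultivar grown hydroponically on 0.5 or 2.5 mM nitrate, had been measured on 84 single-colour Cy3 arrays, 3 for each of 28 groups of tissue, nitrate level and harvest day. The arrays lay on 22 slides of up to 4 positions and were scanned in 4 sessions. Replicates were taken as the separate arrays of a group, and the labels give no numbers that link them across groups.

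Per the file headers, spots were quantified with Feature Extraction 10.7.3.1, whose deposited processed signal is an intensity after background subtraction and detrending within the array, with no scaling between arrays. The deposited mean signal and local background are also intensity values, per pixel. The deposited flags, of an other unit, are 0 or 1 per spot for being well above background, saturated or an outlier. The authors also deposited a series table in log2, with 1 value per group for 37987 probes and column medians from 8.03 to 8.07. It correlated at r = 0.992 to 0.997 across probes with the group means of the scanner values, and how it was scaled, centred or summarised is not stated. The submitters' processing notes name limma without a version or a role.

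Each array held 45220 spots for 42858 non-control probes of 60 bases. No spot was saturated, and 4773 spots marked as outliers by the scanner software over all arrays were left out. The log2 of the processed signal was taken relative to the 75th percentile of the array with a floor of 1 after scaling, and spots of a probe were averaged. Probes were tested if well above background on all 3 arrays of at least 1 group of the fit. Group means were fitted with limma 3.58.1 in R 4.3.3, in separate fits of 42 arrays per tissue and a joint fit of 84 arrays for the contrasts between tissues. Differences were tested with moderated statistics, two-sided, and the Benjamini-Hochberg adjusted p over all probes tested was compared with 0.05. Nitrate differences are 0.5 minus 2.5 mM, developmental ones day 36 minus day 11 and tissue ones root minus shoot. Interactions and change over days were tested with a moderated F statistic. Errors of differences are standard errors of the fit. For a probe above background on fewer than 50% of the arrays of its dimmer arm, the fold is a lower bound against the dimmest signal called above background on those arrays, or the probe's own signal where that was brighter. This bound was extended from arms with no such array after the data were examined.

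No table or file column pairs a probe with a gene. The files hold 0 probes whose description names a product, and 0 probes matched the reference table of gene symbols. The 45 gene lists fixed before the data were examined therefore had no member and could not be tested. Probes were named by the rule fixed in advance for that case, the 2 that rose and the 2 that fell most among those past the threshold, with the same sign on at least 6 of 7 days for averaged effects. The rule was applied to the averaged effects, to each day, to day 36 against day 11 and to root against shoot, and the interactions and the nitrate-by-tissue contrast were given as counts because the rule names probes that rose or fell and these test differences between effects.

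Alternatives fixed before the data were examined were normexp background correction with an offset of 50, quantile normalization, no filter on dim probes, the slide as a random block (statmod 1.5.0), trended and robust eBayes, 1 fit over all 84 arrays, the deposited series values, each day left out, each array left out and, for the averaged effects, the slide as a fixed block. Alternatives chosen after seeing the data were the scan session, the slide for other results and the array position as fixed blocks, the removal of each array's trend over 20 GC classes, and covariates for 1 or 2 array axes, the control-probe pattern and the detection share, the last also with the session. Array axes are the leading components of the spread within groups. The control-probe pattern is the leading component, within groups, of the relative levels of the 8 spiked-in positive-control probes with a median signal above 100. The detection share is the share of probes above background on an array. Counts were also taken within each scan session over the days with both nitrate levels in it, likewise after seeing the data.

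For results of whole models, 100 splits of the arrays, the real one included, were drawn with a fixed seed, and all 10 splits were taken for 3 arrays against 3. The correlation of array axes with the control-probe pattern was tested with 1e+05 permutations within groups. The code was tested on simulated data with 36693 probes. There, a log2 difference of 1 in the averaged effect was recovered for 93% of changed probes in root and 96% in shoot, and on a single day for 38% and 41%, with at most 13 false calls. A log2 difference of 1 on a single day was recovered by the interaction test for 6% and 8%, and a difference of 2 for 52% and 42%. The simulated noise was independent between probes and arrays, whereas 1 array axis held 44.7% of the real root spread within groups. The simulated shares and false calls therefore do not carry over to the real arrays. Tables were handled with data.table, version 1.17.8, and figures drawn with matplotlib 3.10.9. The 75th percentile of the signal was 1605 to 3291 on root arrays and 363.7 to 2183 on shoot arrays, and the number of arrays limits the precision of all values.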

Results

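The series followed the dwarf maize cultivar Gaspe Flint through its life cycle in hydroponic culture on 0.5 mM or 2.5 mM nitrate. Total transcript levels were measured in the whole root and in the youngest fully emerged leaf blade, which the labels call shoot. Plants were harvested on 7 days (11, 15, 18, 22, 29, 32 and 36), and each of the 28 combinations of tissue, nitrate level and day had 3 biological replicates, each on 1 array. Each of the 84 arrays carried 42858 non-control probes of 60 bases. The 75th percentile of the processed signal lay between 1605 and 3291 intensity units on root arrays and between 363.7 and 2183 on shoot arrays. Between 73.72% and 88.12% of the probes were well above background on root arrays, and between 70.57% and 89.26% on shoot arrays. Replicates of a group correlated, across probes, at r = 0.972 to 0.995 in root and 0.963 to 0.994 in shoot, where probes are not independent replicates. The number of arrays limits the precision of every value below. The files pair no probe with a gene of the reference table, so results are given by probe identifier and sequence.

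The first comparison asked which root transcripts differed between the nitrate levels over the whole life cycle, as the mean over the 7 days of 0.5 mM minus 2.5 mM. Probe P1000236495 (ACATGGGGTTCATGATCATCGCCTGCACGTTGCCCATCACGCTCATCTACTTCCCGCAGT) was 4.64-fold higher at 0.5 mM, a log2 difference of 2.21 ± 0.17 (SE, 21 arrays against 21), with a limma adjusted p of 1.25e-09. Its mean was above that at 2.5 mM on 7 of 7 days, and all 42 arrays measured it above background. P1000229133 (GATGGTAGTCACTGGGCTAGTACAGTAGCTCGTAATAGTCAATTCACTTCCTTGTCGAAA) was at least 2.18-fold higher, on 7 of 7 days (limma adjusted p = 0.0151), and was above background on 17 of the 21 arrays at 0.5 mM and on 4 of the 21 at 2.5 mM. P1000230513 (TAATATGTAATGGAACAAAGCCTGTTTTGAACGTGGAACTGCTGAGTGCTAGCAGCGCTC) fell by 2.51 ± 0.52 at 0.5 mM, on 7 of 7 days (limma adjusted p = 0.00241), and was above background on 15 of 21 and 18 of 21 arrays. P1000289193 (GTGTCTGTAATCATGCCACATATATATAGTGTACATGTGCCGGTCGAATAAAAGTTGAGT) fell by 2.31 ± 0.40, again on 7 of 7 days and measured on all 42 arrays (limma adjusted p = 0.000379). Of 36904 probes tested, 1411 passed an adjusted p of 0.05, 683 higher and 728 lower at 0.5 mM, and the larger share turned with, among other settings, quantile normalization (822 higher, 617 lower), without the GC trend (997 and 906) and with normexp (356 and 346). Most of these differences were small, with a median absolute log2 difference of 0.366 and 40 probes past 2-fold. Among the 1411, 246 had the same sign on all 7 days and a further 607 on 6 of the 7.

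The root count rose to 3006 without day 11 and fell to 349 without day 29. It was 702 with normexp and 648 in 1 fit over all 84 arrays. With the deposited series values it was 0 (limma, 1109 of 37987 at an unadjusted p below 0.05, fewer than no effect gives). With the scan session as a fixed block 1764 probes passed, 1003 of them shared in sign with the 1411. With the slide as a fixed block 385 passed, 292 of them shared. Of the 4 named probes, the slide block kept the call of P1000236495 (log2 2.03), while P1000229133, P1000230513 and P1000289193 had log2 differences of 1.97, -2.60 and -2.30 and no longer passed (limma adjusted p = 0.417, 0.0861 and 0.112), and P1000229133 did not pass with normexp either (log2 0.47). The same 3 lost their calls with session and detection share together (log2 2.56, -2.31 and -1.95). Without day 15, 22 or 36 P1000229133 also lost its call (log2 2.20, 2.40 and 2.46, limma adjusted p = 0.109, 0.0615 and 0.0506). Within scan session 2, 1789 passed (28 arrays). Sessions 1 and 3 held both levels on day 36 or 32 alone, 1 array at 0.5 mM against 3, and cannot test the average.

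**Figure D1:**
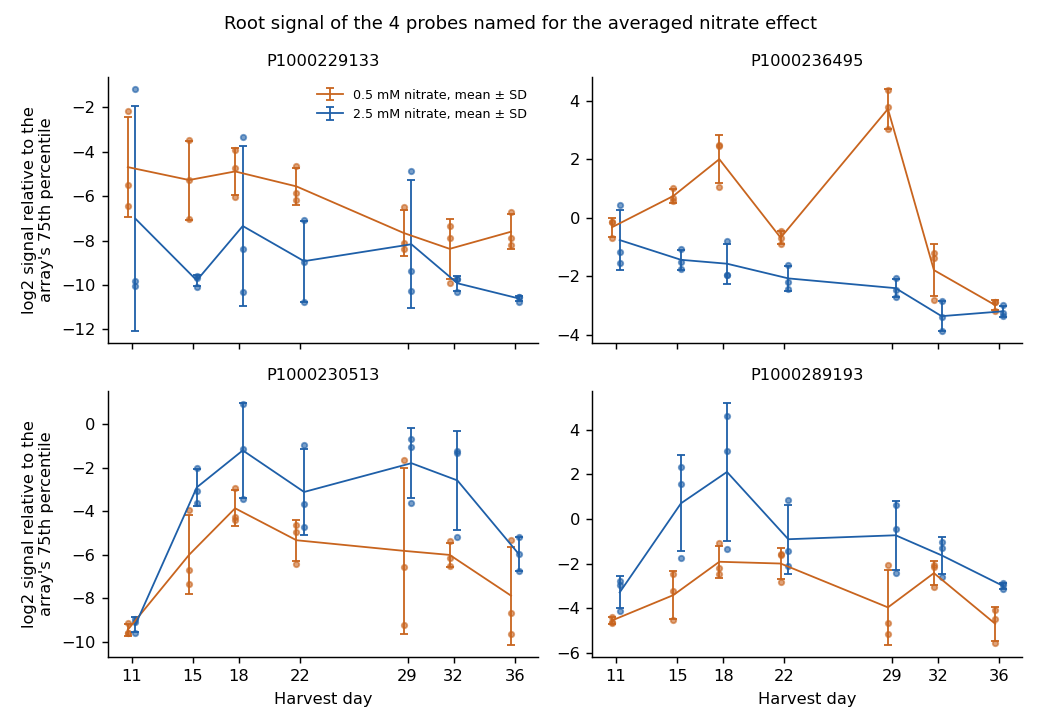
Log2 signal relative to each array's 75th percentile against harvest day for the 4 root probes named for the averaged nitrate effect. Points are single arrays, lines join group means and bars are SDs of 3 arrays. P1000236495 at 0.5 mM reached 3.72 on day 29 and lay at -2.99 on day 36, against -2.41 and -3.20 at 2.5 mM.

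The daily comparisons asked when in the life cycle the root transcripts differed. On day 29, P1000236495 was 69.8-fold higher at 0.5 mM, a log2 difference of 6.13 ± 0.44 (SE, 3 arrays against 3, limma adjusted p = 7.47e-11). P1000232875 (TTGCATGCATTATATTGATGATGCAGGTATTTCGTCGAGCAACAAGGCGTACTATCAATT) was 24.6-fold higher on that day (4.62 ± 0.57, limma adjusted p = 8.94e-07). P1000266653 (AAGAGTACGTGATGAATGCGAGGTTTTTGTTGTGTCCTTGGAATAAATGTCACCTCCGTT) fell by 5.57 ± 0.68 (limma adjusted p = 6.82e-07) and P1000223343 (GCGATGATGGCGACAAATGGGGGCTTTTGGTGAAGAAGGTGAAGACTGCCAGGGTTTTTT) fell by 4.53 ± 0.34 (limma adjusted p = 1.41e-10). For each of the 4 probes, all 3 arrays at 0.5 mM lay beyond all 3 at 2.5 mM. P1000223343 stood at -0.50 at 0.5 mM and 4.03 at 2.5 mM on day 29, and at 4.13 and 4.15 on day 32. P1000266653 likewise stood at -6.47 and -0.90 on day 29, and at 0.82 and 0.17 on day 32. In all, 6601 probes passed on day 29, 2817 higher and 3784 lower, and 2536 of them differed at least 2-fold. The larger share turned with quantile normalization (3881 higher, 3202 lower), with the control-probe pattern as a covariate (2079 and 1901) and without each array's GC trend (3579 and 2464). All 6 arrays of day 29 were in scan session 2, where 10161 passed. With the session as a block 11757 passed, and with the slide as a block 12619.

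The day 29 count depended on single arrays. Without replicate 1, 2 or 3 at 0.5 mM it was 2448, 10699 and 4002, and without replicate 1 or 3 at 2.5 mM it was 3746 and 3209. The count was 3223 with normexp, 3495 in the fit over all 84 arrays and 1699 with the array position on the slide as a block.

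A set of probes was taken from the day 29 difference after the data had been examined. It held 2406 probes that passed on day 29 with the same sign without a covariate, with the control-probe pattern, with 2 array axes, with the session and with the slide, 1171 higher and 1235 lower at 0.5 mM. Of these, 1269 differed at least 2-fold. Signs on the other days were taken from the fit with the control-probe pattern as a covariate. On day 18 91.3% of the 1269 had the sign of day 29, on day 15 85.7%, on day 22 67.5%, on day 11 53.6%, on day 32 53.7% and on day 36 42.1%. Over all root probes and without a covariate, the log2 differences of day 29 correlated at -0.464 with day 18, -0.257 with day 15, -0.00273 with day 22 and 0.615 with day 11. With 2 array axes these were 0.273, 0.259, 0.176 and 0.0753, and with the control-probe pattern 0.129, 0.245, 0.179 and 0.131. Over all probes, days 15 and 18 ran with day 29 weakly and only with these covariates.

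**Figure D2:**
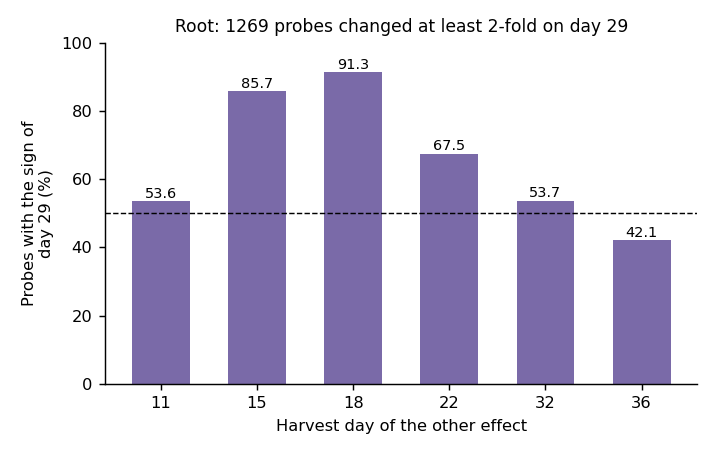
Percent of the 1269 root probes of the day 29 set whose nitrate difference on another harvest day had the sign of day 29. The signs are from the fit with the control-probe pattern as a covariate. The dashed line marks 50%, and days 15 and 18 stood at 85.7% and 91.3%. Over all root probes the correlation with day 29 was -0.257 for day 15 and -0.464 for day 18 without a covariate, and 0.245 and 0.129 with the control-probe pattern.

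On day 11 the largest root differences were in P1000279002 (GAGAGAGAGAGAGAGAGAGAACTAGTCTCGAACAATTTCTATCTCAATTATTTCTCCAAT), higher at 0.5 mM by 4.70 ± 0.88 (limma adjusted p = 0.000238), and P1000248044 (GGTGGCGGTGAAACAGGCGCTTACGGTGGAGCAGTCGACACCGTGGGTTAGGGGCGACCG), higher by 4.60 ± 1.59 (limma adjusted p = 0.0169, 2 arrays against 3). P1000279002 was above background on 2 of the 3 arrays at 2.5 mM, and its difference fell to 1.38 with the control-probe pattern and 1.34 with 2 array axes. It lost its call with the detection share (log2 2.09, limma adjusted p = 0.0673), alone or with the session. P1000264620 (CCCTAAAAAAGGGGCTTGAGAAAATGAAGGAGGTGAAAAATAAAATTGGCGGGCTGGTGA) was at least 3.8-fold lower at 0.5 mM and P1000272312 (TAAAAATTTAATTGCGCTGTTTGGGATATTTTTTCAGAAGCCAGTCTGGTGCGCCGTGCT) at least 2.44-fold lower (limma adjusted p = 0.000448 and 0.000799). Neither was above background on an array at 0.5 mM. On day 18 P1000236495 was again higher at 0.5 mM, by 3.57 ± 0.44 (limma adjusted p = 3.84e-05), and so was P1000288064 (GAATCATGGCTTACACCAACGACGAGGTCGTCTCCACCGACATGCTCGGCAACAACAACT), by 4.03 ± 1.04 (limma adjusted p = 0.024). On that day P1000289193 fell by 4.02 ± 1.07 (limma adjusted p = 0.0266), and P1000247809 (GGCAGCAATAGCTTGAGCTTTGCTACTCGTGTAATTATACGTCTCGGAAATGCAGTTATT) was at least 3.64-fold lower (limma adjusted p = 1.15e-05). For P1000288064 and P1000289193, 2 of the 3 arrays at 0.5 mM lay beyond all 3 at 2.5 mM, and for P1000236495 and P1000247809 all 3 did. P1000288064 lost its call without replicate 1 or 2 at 0.5 mM or replicate 3 at 2.5 mM (log2 3.62, 3.56 and 3.03), and P1000289193 without replicate 1 or 3 at 0.5 mM or replicate 1 or 3 at 2.5 mM (log2 -3.75, -4.43, -2.77 and -3.54). With the slide as a block none of the 4 probes of day 18 passed, though the log2 differences stayed at 3.36 for P1000236495, 3.67 for P1000288064, -5.75 for P1000289193 and -4.08 for P1000247809 (limma adjusted p = 0.057, 0.591, 0.479 and 0.107). With the control-probe pattern P1000288064 (2.69) and P1000289193 (-4.34) lost their calls on day 18. On day 11 P1000248044 lost its call without replicate 1 at 0.5 mM (log2 2.93). With normexp P1000247809 stood at -0.41 on day 18 and lost its call (limma adjusted p = 0.808), as did P1000288064 (2.16), and P1000264620 (-1.16) and P1000272312 (-0.93) lost theirs on day 11 (limma adjusted p = 0.0655, 0.218 and 0.304), with P1000248044 at an adjusted p of 0.0517.

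The number of root probes past the threshold was 20376 on day 11 (6089 higher, 14287 lower) and 3388 on day 18 (1590 higher, 1798 lower). On day 11 the shares were near equal with quantile normalization (7866 higher, 8292 lower), and the higher one was larger without the GC trend (9214 and 7785). On day 18 the higher share was the larger one with the session as a block (8211 and 4825), within session 2 (2439 and 1362), with session and detection share (3046 and 2363), 2 array axes (269 and 235), 1 array axis (215 and 198), the control-probe pattern (104 and 91) or the array position (89 and 85), and without replicate 3 at 0.5 mM (201 and 149) or replicate 1 or 3 at 2.5 mM (3332 and 2960, 109 and 92). The count was 91 on day 15, 3 on day 22, 58 on day 32 and 37 on day 36. Without a covariate the effects of days 11 and 18 ran against each other, at r = -0.748 over all root probes, but at -0.15 with 2 array axes and -0.245 with the control-probe pattern. Of the probes lower on day 11, 1133 were higher on day 18 where independent lists would share 615.6, and 19 were lower on both days against 696.1. The share of probes above background moved with the day 11 effect, at 74.5% ± 1.23 (SD, n = 3) at 0.5 mM and 82.1% ± 0.542 at 2.5 mM. A plant-independent measure moved with it too. The pattern of 8 spiked-in control probes had a mean score of -0.708 ± 0.651 at 0.5 mM and 1.61 ± 0.548 at 2.5 mM on day 11 (SD, n = 3 each), and of 0.896 ± 0.367 and -0.954 ± 0.772 on day 18. With that pattern as a covariate, 2971 probes passed on day 11, 195 on day 18 and 3980 on day 29. Of the 4 probes of day 11, P1000248044 then changed sign (-0.98), and P1000264620 (-2.68) and P1000272312 (-1.78) kept theirs, but the 3 no longer passed (limma adjusted p = 0.576, 0.0612 and 0.171). Within scan session 2, 21429 passed on day 11 and 3801 on day 18. With the session as a block 22248 and 13036 passed, and with the slide as a block 21676 and 8. Single arrays decided the day 18 count. It was 174 and 350 without replicate 1 or 3 at 0.5 mM, and 6292, 673 and 201 without replicate 1, 2 or 3 at 2.5 mM.

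On the other days the root calls were few, and their number depended on single arrays and on the model. Leaving out 1 array put it at 8 to 91 on day 15, 1 to 2 on day 22, 17 to 903 on day 32 (903 without replicate 3 at 0.5 mM) and 0 to 2592 on day 36 (2592 without replicate 1 at 0.5 mM). With 2 array axes as covariates 288, 10, 201 and 264 passed, and with dim probes tested too 402 passed on day 36. On day 15 P1000215654 (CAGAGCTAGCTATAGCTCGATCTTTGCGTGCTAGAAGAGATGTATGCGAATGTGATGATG) was at least 1.94-fold higher at 0.5 mM (limma adjusted p = 1.41e-07) and P1000312260 (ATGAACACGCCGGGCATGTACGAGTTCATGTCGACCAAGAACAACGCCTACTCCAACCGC) was higher by 3.37 ± 0.66. P1000266653, named above for day 29, fell by 3.61 ± 0.68, and P1000234694 (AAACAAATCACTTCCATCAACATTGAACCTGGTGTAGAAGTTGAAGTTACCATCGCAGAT) was at least 4.06-fold lower. The 3 probes of day 22 were P1000289149 (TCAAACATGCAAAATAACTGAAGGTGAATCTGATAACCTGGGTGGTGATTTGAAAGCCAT), higher by 1.30 ± 0.23, P1000286390 (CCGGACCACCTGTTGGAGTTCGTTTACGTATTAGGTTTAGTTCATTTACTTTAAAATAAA), which fell by 1.92 ± 0.22 (limma adjusted p = 3.94e-05), and P1000217375 (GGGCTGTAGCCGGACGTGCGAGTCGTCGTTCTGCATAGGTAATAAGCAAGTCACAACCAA), which fell by 1.73 ± 0.29. P1000286390 also fell on day 32, by 1.24 ± 0.22 (limma adjusted p = 0.00973), as did P1000243952 (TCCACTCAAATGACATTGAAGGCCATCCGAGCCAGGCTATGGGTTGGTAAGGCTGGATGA), by 1.52 ± 0.31. P1000303818 (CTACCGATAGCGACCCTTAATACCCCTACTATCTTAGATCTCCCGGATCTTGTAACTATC) was at least 2.86-fold and P1000269778 (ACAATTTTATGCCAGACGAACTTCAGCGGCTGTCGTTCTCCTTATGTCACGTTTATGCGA) at least 3.12-fold higher on day 32. On day 36 P1000235506 (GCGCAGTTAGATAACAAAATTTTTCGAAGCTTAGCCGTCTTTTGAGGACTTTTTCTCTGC) was at least 10.8-fold higher and P1000219531 (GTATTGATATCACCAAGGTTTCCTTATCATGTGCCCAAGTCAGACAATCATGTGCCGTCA) higher by 3.56 ± 0.61, while P1000256434 (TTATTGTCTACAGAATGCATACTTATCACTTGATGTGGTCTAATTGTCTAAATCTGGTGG) and P1000238913 (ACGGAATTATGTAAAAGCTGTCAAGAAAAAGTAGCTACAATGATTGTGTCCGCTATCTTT) fell by 1.96 ± 0.37 and 1.95 ± 0.41. With normexp none of these calls held but those of P1000266653 on day 15 and P1000286390 on days 22 and 32. P1000235506 then changed sign (-0.07), P1000215654 stood at 0.65, P1000234694 at -0.48, P1000303818 at 1.21 and P1000269778 at 1.25. With the slide as a block none of the 4 probes of day 36 passed. Of these 15 calls, those of P1000215654 on day 15 and P1000286390 on day 22 held without each of the 6 arrays of the day in turn. The other 13 ended without at least 1 array, with adjusted p values up to 0.616 (limma, P1000238913), and P1000286390 on day 22 alone passed under each alternative setting run.

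Several of these probes were called with the opposite sign on another day. P1000286390 was 2.15-fold higher at 0.5 mM on day 29 (log2 1.10, limma adjusted p = 0.000806), P1000243952 was higher on day 29 (0.96), P1000217375 on day 18 (1.34) and P1000238913 on day 11 (1.24). On day 11 P1000219531 fell by 2.87, P1000269778 fell by 2.22 and P1000289149 fell by 1.17. The scan session was partly confounded with nitrate on the last 2 days. On day 36 all 3 arrays at 2.5 mM were in session 1, against 1 of 3 at 0.5 mM, and on day 32 all 3 at 2.5 mM were in session 3, against 1 of 3 at 0.5 mM. With the session as a fixed block P1000219531 (3.23), P1000256434 (-1.98) and P1000238913 (-0.93) lost their calls on day 36, as did P1000243952 (-0.95) and P1000286390 (-1.38) on day 32 (limma adjusted p = 0.282, 0.322, 0.916, 0.366 and 0.0518).

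**Figure D3:**
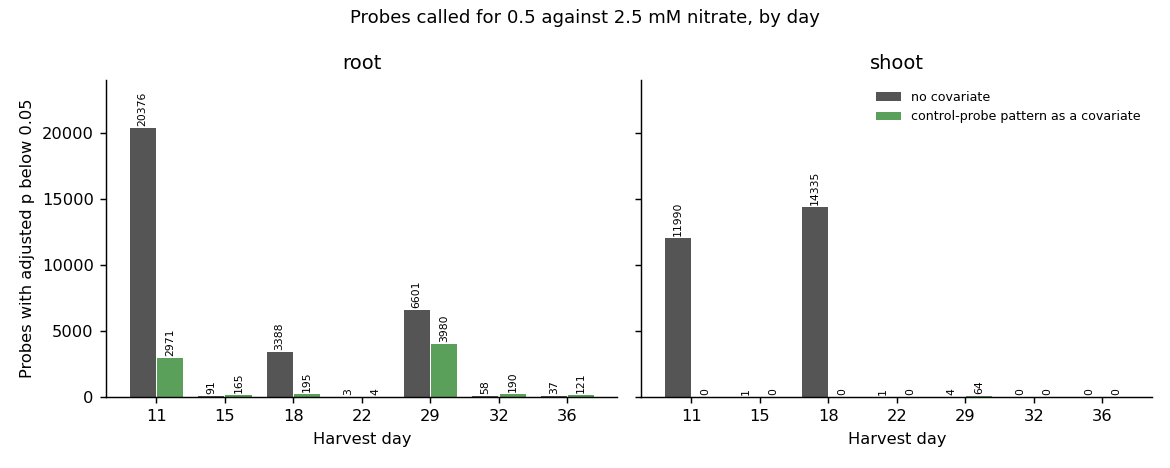
Number of probes with an adjusted p below 0.05 for 0.5 against 2.5 mM nitrate on each harvest day, in root and shoot, without a covariate (grey) and with the control-probe pattern as a covariate (green). The root day 29 count was 6601 without and 3980 with the covariate, and the shoot counts of days 11 and 18 were 11990 and 14335 without it and 0 with it.

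In the leaf blade, the averaged comparison asked the same question. P1000272808 (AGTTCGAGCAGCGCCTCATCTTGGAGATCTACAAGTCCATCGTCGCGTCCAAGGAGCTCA) was 2.89-fold higher at 0.5 mM (log2 1.53 ± 0.41, SE, 21 arrays against 21, limma adjusted p = 0.0114). P1000237772 (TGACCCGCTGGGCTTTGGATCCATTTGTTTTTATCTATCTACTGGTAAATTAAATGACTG) was higher by 1.44 ± 0.39 (limma adjusted p = 0.0118), and both were higher on 7 of 7 days. P1000239901 (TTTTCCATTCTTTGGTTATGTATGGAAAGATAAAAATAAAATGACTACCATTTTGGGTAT) was at least 2.65-fold lower, on 6 of 7 days (limma adjusted p = 0.0227), and was above background on 10 of 21 arrays at 0.5 mM and 16 of 21 at 2.5 mM. P1000294405 (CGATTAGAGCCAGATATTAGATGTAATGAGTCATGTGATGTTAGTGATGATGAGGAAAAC) was at least 2.03-fold lower, on 7 of 7 days (limma adjusted p = 0.00237), with 10 of 21 and 20 of 21 arrays above background. Of 36857 probes tested, 10982 passed, 6456 higher and 4526 lower at 0.5 mM, and 164 of them past 2-fold. The lower share was the larger one with normexp (745 higher, 1137 lower), the session as a block (11 and 38), the control-probe pattern (20 and 98), session and detection share (23 and 60) and 1 array axis, and without day 11 (123 and 318) or day 18 (28 and 94). The median absolute log2 difference of the called probes was 0.453, and 1839 had the same sign on all 7 days.

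Scan sessions held fewer leaf blade days and arrays, which alone can end calls. Session 1 had 0 calls (12 arrays, limma, 4423 at an unadjusted p below 0.05). Session 3, without day 18, had 1 (23 arrays, limma, 1955). The effects within each session correlated at r = 0.717 across probes with the averaged effect, of which their arrays are a part. With the session as a block 49 passed (limma, 8134 at an unadjusted p below 0.05), and with the slide as a block 0 passed (limma, 1873). The sessions were spread unevenly, with 10 arrays at 0.5 mM and 5 at 2.5 mM in session 1 and 9 and 16 in session 3. The count was 118 with the control-probe pattern as a covariate, 441 without day 11, 3892 without day 15, 122 without day 18, 7261 without replicate 1 of day 15 at 0.5 mM and 0 with the deposited series values (limma, 8060 at an unadjusted p below 0.05). Of the named probes, P1000294405 alone passed with the control-probe pattern as a covariate (limma adjusted p = 0.0352), and none passed with the session as a block, where the log2 differences were 0.96, 0.84, -0.52 and -1.34 in the order named. Without day 18 P1000272808 (1.44), P1000237772 (1.12) and P1000239901 (-2.02) lost their calls (limma adjusted p = 0.0982, 0.124 and 0.113). P1000272808 also lost it without day 11 (1.52), and P1000239901 without day 11 (-2.09), 15 (-2.00) or 29 (-1.66). With normexp P1000272808 (0.97), P1000239901 (-0.71) and P1000294405 (-0.24) lost their calls (limma adjusted p = 0.0716, 0.253 and 0.864).

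By day, most leaf blade calls without a covariate were on days 11 and 18. P1000298349 (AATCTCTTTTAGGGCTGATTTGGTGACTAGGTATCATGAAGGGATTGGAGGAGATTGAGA) was higher at 0.5 mM on day 11, by 4.68 ± 1.23 (limma adjusted p = 0.00871), and on day 18, by 4.49 ± 1.23 (limma adjusted p = 0.00607). P1000233537 (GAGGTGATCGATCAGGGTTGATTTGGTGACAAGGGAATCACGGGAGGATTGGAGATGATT) was higher on day 11 by 4.10 ± 0.99 (limma adjusted p = 0.00763), and P1000310302 (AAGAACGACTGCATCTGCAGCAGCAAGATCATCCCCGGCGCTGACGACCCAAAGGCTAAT) on day 18 by 5.86 ± 2.22 (limma adjusted p = 0.0366). On day 11 P1000304899 (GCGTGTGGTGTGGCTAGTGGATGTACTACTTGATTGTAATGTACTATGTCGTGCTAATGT) fell by 4.86 ± 0.88, measured on 1 array at 2.5 mM, which is assumed to vary like the other groups, and P1000270020 (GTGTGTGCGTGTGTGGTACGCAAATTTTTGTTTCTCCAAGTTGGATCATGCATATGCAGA) fell by 4.00 ± 1.19, measured on 2 (limma adjusted p = 0.00643 and 0.0146). On day 18 P1000274847 (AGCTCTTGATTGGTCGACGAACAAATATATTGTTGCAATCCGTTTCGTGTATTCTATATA) fell by 3.65 ± 0.79 and P1000303602 (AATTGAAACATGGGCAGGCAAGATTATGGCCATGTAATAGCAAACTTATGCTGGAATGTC) was at least 6.69-fold lower (limma adjusted p = 0.00196 and 0.00179). P1000303602 was above background on 1 of the 3 arrays at 0.5 mM. P1000310302 lost its call without any of 5 arrays, namely replicates 1, 2 and 3 at 0.5 mM (log2 5.82, 5.90 and 5.86) and replicates 1 and 3 at 2.5 mM (log2 4.80 and 4.25), and P1000270020 without replicate 2 at 2.5 mM (log2 -3.55). For each of these probes all 3 arrays at 0.5 mM lay beyond those measured at 2.5 mM. None of them passed with the control-probe pattern as a covariate or with the slide as a block. With the slide block the log2 differences on day 11 were 3.48 for P1000298349, 3.15 for P1000233537, -0.73 for P1000304899 and -3.79 for P1000270020, and on day 18 6.35 for P1000310302, 3.64 for P1000298349, -1.98 for P1000274847 and -2.00 for P1000303602. With the control-probe pattern they were 0.35, 0.72, -2.70 and -0.46 on day 11, and 6.60, 0.37, -2.79 and -2.44 on day 18. With normexp P1000303602 stood at -0.15 on day 18 (limma adjusted p = 0.863), and P1000310302 (5.06) and the 4 probes of day 11 lost their calls too, at adjusted p values from 0.0566 to 0.0781.

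The counts in the leaf blade were 11990 on day 11 (8391 higher, 3599 lower) and 14335 on day 18 (10131 higher, 4204 lower). They were 1 on days 15 and 22, 4 on day 29, and 0 on days 32 and 36. There limma gave 1116 and 805 probes at an unadjusted p below 0.05 (3.03% and 2.18%), fewer than no effect gives. The larger share turned on day 11 without the GC trend (3161 higher, 3398 lower) and on day 18 with quantile normalization (6921 higher, 7791 lower) and with 1 array axis as a covariate (1403 and 1866). The day 29 count was 729 without replicate 3 at 0.5 mM, 1014 in the fit over all 84 arrays and 64 with the control-probe pattern as a covariate, and the day 22 count was 272 in the fit over all 84 arrays. Without a covariate the called probes of days 11 and 18 moved alike, and over all probes the effects of the 2 days correlated at r = 0.795, but at 0.161 with 2 array axes and 0.399 with the control-probe pattern. Of the called probes, 6270 were higher on both days, where independent lists would share 2306, and 2019 were lower on both against 410.4. The day 11 count was 0 with normexp (limma, 6365 at an unadjusted p below 0.05) and 4461 with the session as a block, and it was 9585 within session 3. The day 18 count was 4967 within session 1 and 14596 with the session as a block. Both days had 0 with the slide as a block (limma, 7735 and 5966 at an unadjusted p below 0.05) and with the control-probe pattern as a covariate (limma, 1058 and 5997). The control-probe pattern differed between the levels here too, with mean pattern scores of 1 ± 0.324 at 0.5 mM and -1.16 ± 0.15 at 2.5 mM on day 11 and of 1.24 ± 0.265 and -0.811 ± 0.545 on day 18 (SD, n = 3 each). Without replicate 3 at 0.5 mM, or replicate 1 or 2 at 2.5 mM, the day 11 count was 4984, 5586 and 7966, and without replicate 3 of day 18 at 2.5 mM the day 18 count was 7748.

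On the other days the leaf blade calls were single probes. P1000269315 (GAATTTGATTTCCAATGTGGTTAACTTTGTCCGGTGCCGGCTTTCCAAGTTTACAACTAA) was at least 1.64-fold higher on day 15 (limma adjusted p = 0.0467), and changed sign with normexp (-0.84). P1000227203 (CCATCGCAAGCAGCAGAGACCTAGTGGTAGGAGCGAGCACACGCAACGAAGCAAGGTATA) fell by 2.29 ± 0.37 on day 22 (limma adjusted p = 0.0334). On day 29 P1000303685 (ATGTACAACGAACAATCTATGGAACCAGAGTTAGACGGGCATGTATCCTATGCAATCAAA) was higher by 1.21 ± 0.19, though on day 11 it fell by 0.55 (limma adjusted p = 0.0302), P1000258600 (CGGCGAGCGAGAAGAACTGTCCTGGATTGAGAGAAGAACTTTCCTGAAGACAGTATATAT) fell by 2.83 ± 0.51 and P1000302207 (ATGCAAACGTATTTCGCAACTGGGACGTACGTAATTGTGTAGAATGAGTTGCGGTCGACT) fell by 2.05 ± 0.33 (limma adjusted p = 0.015, 0.037 and 0.015). The fourth probe of day 29, P1000220010, fell by 1.53 (limma adjusted p = 0.0183) and was named after its values were seen. Each of the 5 probes named by rule lost its call without at least 3 of the 6 arrays of its day, and none of the 5 passed with normexp or with the slide as a block. With the block the log2 differences were 3.44 for P1000269315, -1.77 for P1000227203, 0.97 for P1000303685, -2.46 for P1000258600 and -1.07 for P1000302207.

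The developmental comparison set day 36 against day 11 in root, over both nitrate levels. P1000293033 (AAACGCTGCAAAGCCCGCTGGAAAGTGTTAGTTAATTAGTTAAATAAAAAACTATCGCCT) was at least 4730-fold higher on day 36 (6 arrays against 6, limma adjusted p = 8.97e-14), with 1 of the 6 arrays of day 11 above background. P1000254194 (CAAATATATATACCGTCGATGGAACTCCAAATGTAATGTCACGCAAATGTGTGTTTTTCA) was above background on no array of day 11 and was at least 952-fold higher on day 36 (limma adjusted p = 3.44e-13). P1000293033 rose early, reaching 6.80 at 0.5 mM and 6.38 at 2.5 mM on day 22, whereas P1000254194 stood at -9.53 and -10.63 on day 22 and at 2.98 and 1.79 on day 32. P1000209757 (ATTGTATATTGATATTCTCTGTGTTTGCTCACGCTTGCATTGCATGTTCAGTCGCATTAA) fell by 6.58 ± 0.46 on the log2 scale (SE, limma adjusted p = 4.35e-13), most of it after day 32, when it stood at 2.29 and 2.95 against -4.99 and -5.36 on day 36. P1000221689 (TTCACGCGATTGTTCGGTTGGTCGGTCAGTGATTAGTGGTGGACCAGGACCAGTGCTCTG) fell by 5.01 ± 0.32 (limma adjusted p = 9.33e-14). For each probe all 6 arrays of day 36 lay beyond all 6 of day 11. In root 19903 probes passed, 11131 higher and 8772 lower on day 36, with 5996 past 2-fold. With the detection share as a covariate the lower share was the larger one. Over all 7 days 29267 probes changed, and 13112 of them had a range of at least 2-fold between daily means. Of the 29267, 8815 were highest on day 22 and 6556 on day 36. Root day 22 also had control-probe pattern scores of 0.64 at 0.5 mM and 0.621 at 2.5 mM. On that day 85.1% and 86.6% of probes were above background. The peak days were not taken with a covariate, so timing and differences between arrays cannot be told apart there.

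All root arrays of day 11 were in scan session 2, and those of day 36 were in sessions 1 and 3, so no session held both days. With the session as a block 17793 probes passed and shared 8900 of the calls in sign, and the 4 named probes kept their direction with adjusted p values from 7.97e-05 to 0.00259 (limma). With the slide as a block 10667 passed, and with session and detection share together 83 passed. In that model none of the 4 passed (limma adjusted p from 0.16 to 0.405), with log2 differences of 13.69 for P1000293033, 13.73 for P1000254194, -6.95 for P1000209757 and -3.10 for P1000221689.

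In the leaf blade, P1000236240 (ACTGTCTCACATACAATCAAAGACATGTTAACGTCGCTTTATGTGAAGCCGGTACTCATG) was at least 2490-fold higher on day 36 than on day 11, and P1000311598 (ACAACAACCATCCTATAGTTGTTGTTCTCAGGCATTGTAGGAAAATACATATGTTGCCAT) at least 1820-fold higher (limma adjusted p = 2.01e-15 and 3.11e-15). Neither was above background on any array of days 11, 15 or 18. P1000236240 stood at -3.47 at 0.5 mM and -6.78 at 2.5 mM on day 22, and at 4.24 and 3.49 on day 36. P1000311183 (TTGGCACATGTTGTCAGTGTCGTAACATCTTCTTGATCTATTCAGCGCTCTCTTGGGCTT) fell by 11.39 ± 0.70 (limma adjusted p = 3.69e-14), from 7.26 and 7.25 on day 11 to -4.44 and -3.83 on day 36, with 5 of the 6 arrays of day 36 above background. P1000227026 (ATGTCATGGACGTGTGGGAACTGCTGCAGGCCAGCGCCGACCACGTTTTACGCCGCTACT) fell by 8.94 ± 0.70 (limma adjusted p = 7.21e-12). For each probe all 6 arrays of day 36 lay beyond all 6 of day 11. In the leaf blade 18400 probes passed, 8104 higher and 10296 lower on day 36 (the larger share turned without the GC trend, at 9850 and 9427, and with 1 or 2 array axes), and 9569 of them past 2-fold. Over all days 31080 changed, 19705 of them with a range of at least 2-fold, and 8165 were highest on day 29. Shoot day 29 also had control-probe pattern scores of 0.738 at 0.5 mM and 1.28 at 2.5 mM, with 82.4% and 87.4% of probes above background. This peak was not taken with a covariate either. The count was 13413 within scan session 3 (8 arrays), 16414 with the session as a block (15462 calls shared in sign), 10635 with the slide as a block and 10871 with normexp. Probes that fell in the leaf blade were often higher in leaf blade than in root, with 6233 such probes against 4818 from independent lists. In root 5892 of the probes that fell were higher in root than in leaf blade, against 3957.

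**Figure D4:**
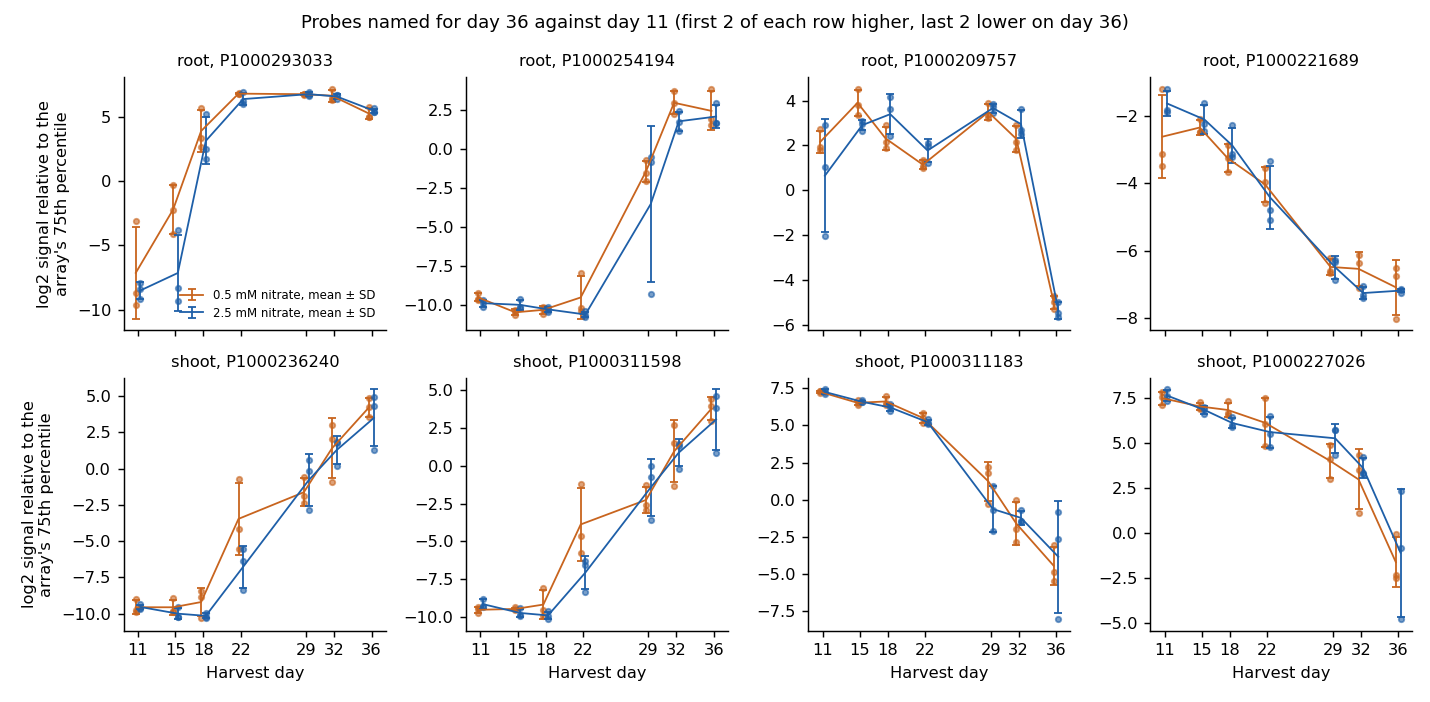
Log2 signal relative to each array's 75th percentile against harvest day for the probes named for day 36 against day 11, in root (upper row) and shoot (lower row), by nitrate level. Points are single arrays, lines join group means and bars are SDs of 3 arrays. P1000236240 in shoot stood at 4.24 at 0.5 mM and 3.49 at 2.5 mM on day 36.

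The tissue comparison set the mean of the 14 root groups against that of the 14 shoot groups. P1000267259 (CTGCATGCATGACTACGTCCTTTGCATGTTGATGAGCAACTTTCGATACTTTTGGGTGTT) was at least 7040-fold higher in root (42 arrays against 42, limma adjusted p = 6.1e-48) and P1000251127 (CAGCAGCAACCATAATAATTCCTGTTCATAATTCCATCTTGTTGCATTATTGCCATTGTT) at least 6580-fold (limma adjusted p = 2.4e-63). They were above background on 13 and 7 of the 42 shoot arrays. P1000299949 (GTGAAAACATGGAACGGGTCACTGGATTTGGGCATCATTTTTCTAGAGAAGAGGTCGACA) was at least 27600-fold lower in root and P1000298433 (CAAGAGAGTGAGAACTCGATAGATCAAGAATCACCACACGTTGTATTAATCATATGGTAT) at least 25400-fold (limma adjusted p = 4.83e-68 and 5.41e-54). They were above background on 5 and 17 of the 42 root arrays. For each probe all 42 root arrays lay beyond all 42 shoot arrays. Of 38123 probes, 33982 differed, 16650 higher in root and 17332 higher in shoot. Among these, 1542 were at least 16-fold higher in root and 1561 at least 16-fold higher in shoot. There were 100 probes above background on all 42 root arrays and on no shoot array, and 43 with the opposite pattern. The split between the tissues moved with normexp, to 12146 higher in root and 21500 in shoot, and the larger share turned with 1 or 2 array axes. Within scan sessions 1 and 3 the counts were 20813 (7 arrays) and 27164 (13 arrays), and with the session and the slide as blocks they were 29617 and 27325.

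The nitrate effects of the 2 tissues were compared directly. The averaged effects correlated at r = 0.179 across the 35638 probes tested in both, which are not independent replicates, and at -0.264 with the session as a block, 0.257 with the control-probe pattern and 0.139 with 2 array axes. Of the probes lower at 0.5 mM in root, 199 were also lower in the leaf blade, where independent lists would share 84.72, and 41 were higher, against 123.2. Of those higher in root, 130 were higher in both tissues, against 117.3. A test of the difference between the tissues passed for 2561 of 38123 probes, 988 with the more positive effect in root and 1573 with the more positive effect in the leaf blade. The larger share turned with normexp (161 and 78), the control-probe pattern (452 and 345), 2 array axes (234 and 181), 1 array axis (578 and 550) and without the GC trend (890 and 678). That count was 504 with the session as a block, 235 with the slide as a block, 239 with normexp, 0 within session 1 (limma, 3128 at an unadjusted p below 0.05) and 12 within session 3. Leaving out single arrays put it between 1185 (replicate 1 of shoot, day 15, 0.5 mM) and 4794 (replicate 3 of shoot, day 29, 0.5 mM), and 29 of the 84 arrays moved it by over 1.5-fold. The nitrate effect differed between days for 19985 of 36904 root probes and 9455 of 36868 leaf blade probes, and for 3845 and 0 (limma, 1882 at an unadjusted p below 0.05) with the control-probe pattern as a covariate.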

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

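Tests chosen only after the result was seen were the session and control-probe tests of the shoot averaged effect, the stage test along the change from day 11 to day 36 and the split counts of both averaged effects, and the removal of the GC trend was a setting added after the data were seen.

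The nitrate effect differed between root and shoot for 2561 of 38123 probes by a test of the difference itself. Of 100 splits, the real one included, 2 gave a count as large, and the highest other split gave 6778. That share is under 0.05, but another split passed the real count, so chance is unlikely and not excluded. Between harvest days the effect differed for 19985 of 36904 root probes by an interaction test. There chance is unlikely (1 of 100 splits, the real one, with 9686 as the highest other), though 100 splits can give no smaller share. The effect differed for 9455 of 36868 shoot probes, where chance is unlikely and not excluded (3 of 100 splits, 20809 as the highest other). Other splits with more than 2 times the real count, as for the contrast of tissues and for the shoot interaction, point to a structure of the samples.

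For the averaged effects too, chance is unlikely and not excluded, since other splits passed the real counts. The root count of 1411 was reached by 2 of 100 splits, with 12001 as the highest other, and the shoot count of 10982 by 3 of 100, with 15841. The highest other splits followed the control-probe pattern, with a difference of 0.848 between their arms in root and -1.02 in shoot, against a median absolute difference of 0.195 and 0.189 in splits with at most 100 calls. The real arms differed by -0.00213 in root and 0.622 in shoot. With the pattern as a covariate the root count was 3010, reached by 1 of 100 splits (the real one), with 89 as the highest other.

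The first pattern weighed was the shoot averaged effect of 10982 probes. Without its dimmest array, replicate 2 of day 18 at 0.5 mM, 11116 probes passed, which argues against a single dim array. With the session as a block 49 passed and with the control-probe pattern as a covariate 118, while the effects correlated with those reported at r = 0.892 and 0.805 across probes. These correlations share arrays and do not measure size. The 4 named probes, reported at 1.53, 1.44, -2.08 and -1.85, stood at 0.96, 0.84, -0.52 and -1.34 with the session. With the pattern they stood at 1.28, 1.44, -1.86 and -1.81. Calls thus ended without the effects turning round, in part with smaller effects. Uneven sessions, and hybridisation or labelling that differs between arrays, are candidate explanations for most of the calls. A nitrate response of the leaf blade stays open, as untested.

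The second pattern was that the root effects of days 11, 18 and 29 lay along 1 axis of the spread between replicate arrays, with r across probes of -0.829, 0.814 and -0.687. GC content as the whole source is argued against by the 16999 probes that passed on day 11 without each array's GC trend. A difference in stage inside groups along the change from day 11 to day 36 is argued against by r = -0.0442 across probes between the axis and that change. No scan session held root arrays of both days, and stage differences of another kind, as between neighbouring harvests, were not tested. Over 42 root arrays the axis went with the control-probe pattern within groups (r = 0.958, rho = 0.96, two-sided permutation p = 1e-05 for each, the smallest that the permutations can give, adjusted 4e-05 over 4 relations, and r = 0.953 without the 2 farthest arrays). Hybridisation or labelling that differs between arrays is thus a candidate explanation for the part of these effects along the axis. A nitrate response of the root on these days stays open, as untested.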

How the results depend on the processing

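Of the 16 settings that left out no array and no day, 7 had been planned before the data were examined, and 9 were added in whole or in part after they had been seen, namely the GC trend and 8 models with a covariate or a fixed block. The planned settings, with those that left out a day, gave 160 counts, of which 10 rose and 43 fell by over 1.5-fold from the reported count. The added settings gave 214 counts, of which 98 lay within 1.5-fold, 29 rose further and 87 fell further. The signal over background limits the dim probes, and normexp, which compresses them, moved 20 of 24 counts. The tissue contrast stayed within 1.5-fold under each setting run, and so did its 4 named probes in direction and call. The 4 root probes of day 29 and the 4 shoot probes of day 36 against day 11 likewise kept direction and call under each setting and without each array. With a case being 1 probe under 1 setting and no array left out, the other named probes kept both in 78 of 92 cases for the root averaged effect, 58 of 92 for the shoot averaged effect, 56 of 60 for root day 36 against day 11, 46 of 60 for root day 18, 40 of 59 for root day 11, 41 of 60 for shoot day 18 and 25 of 58 for shoot day 11. On the days with few calls it was 46 of 60 for root day 15, 34 of 45 for root day 22, 37 of 60 for root day 32, 41 of 60 for root day 36, 3 of 15 for shoot day 15, 7 of 15 for shoot day 22 and 21 of 44 for shoot day 29. The direction changed in 7 cases, none past the threshold. P1000248044 in root on day 11 took log2 values of -0.09025 with 2 array axes, -0.18 with 1 array axis, -0.9787 with the control-probe pattern, -2.267 with the detection share and -1.568 with session and detection share together. With normexp P1000235506 in root on day 36 took -0.07369 and P1000269315 in shoot on day 15 took -0.8374.

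The counts outside 1.5-fold were as follows, and the cause was not tested. Normexp with an offset of 50 gave root counts of 702 for the averaged effect, 8762 for day 11, 31 for day 15, 1165 for day 18, 1 for day 22, 3223 for day 29, 7 for day 32, 0 for day 36, 10120 for the interaction and 17670 for change over days. In shoot normexp with an offset of 50 gave 1882 for the averaged effect, 0 for day 11, 0 for day 15, 4825 for day 18, 0 for day 22, 0 for day 29, 10871 for day 36 against day 11, 0 for the interaction and 13153 for change over days, and 239 for the nitrate-by-tissue contrast. Quantile normalization gave root counts of 26 for day 32. In shoot quantile normalization gave 0 for day 15, 0 for day 22, 39 for day 29 and 5990 for the interaction. Testing dim probes too gave root counts of 8 for day 22 and 402 for day 36, and 0 for shoot day 15. For shoot days 15 and 29 the slide as a random block gave 0 and 2, and trended and robust eBayes 0 and 14. A single fit over all 84 arrays gave root counts of 648 for the averaged effect, 28 for day 15, 521 for day 18, 3495 for day 29, 5 for day 32, 24 for day 36 and 13072 for the interaction. In shoot a single fit over all 84 arrays gave 7 for day 15, 272 for day 22, 1014 for day 29, 1 for day 36 and 15446 for the interaction. The deposited series values gave root and shoot counts of 0 for the averaged effect. Leaving out a day gave counts for the averaged effect of 3006 (day 11) and 349 (day 29) in root. In shoot it gave 441 (day 11), 3892 (day 15) and 122 (day 18). The slide as a fixed block gave root counts of 385 for the averaged effect, 198 for day 15, 8 for day 18, 1 for day 22, 12619 for day 29, 28 for day 32 and 10667 for day 36 against day 11. In shoot the slide as a fixed block gave 0 for the averaged effect, 0 for day 11, 0 for day 15, 0 for day 18, 0 for day 22, 0 for day 29, 10635 for day 36 against day 11 and 4747 for the interaction, and 235 for the nitrate-by-tissue contrast. The session as a fixed block gave root counts of 319 for day 15, 13036 for day 18, 11757 for day 29 and 154 for day 32. In shoot the session as a fixed block gave 49 for the averaged effect, 4461 for day 11, 0 for day 15, 14 for day 22 and 0 for day 29, and 504 for the nitrate-by-tissue contrast. The control-probe pattern gave root counts of 3010 for the averaged effect, 2971 for day 11, 165 for day 15, 195 for day 18, 3980 for day 29, 190 for day 32, 121 for day 36 and 3845 for the interaction. In shoot the control-probe pattern gave 118 for the averaged effect, 0 for day 11, 0 for day 15, 0 for day 18, 0 for day 22, 64 for day 29 and 0 for the interaction, and 797 for the nitrate-by-tissue contrast. 2 array axes gave root counts of 3993 for the averaged effect, 3232 for day 11, 288 for day 15, 504 for day 18, 10 for day 22, 201 for day 32, 264 for day 36 and 4993 for the interaction. In shoot 2 array axes gave 0 for the averaged effect, 5 for day 11, 0 for day 15, 0 for day 18, 4 for day 22, 2 for day 29 and 0 for the interaction, and 415 for the nitrate-by-tissue contrast. 1 array axis gave root counts of 3055 for the averaged effect, 4215 for day 11, 180 for day 15, 413 for day 18, 128 for day 32, 170 for day 36 and 4084 for the interaction. In shoot 1 array axis gave 3 for day 11, 0 for day 15, 3269 for day 18, 0 for day 22, 1 for day 29 and 0 for the interaction, and 1128 for the nitrate-by-tissue contrast. The detection share gave root counts of 2141 for the averaged effect, 2675 for day 11, 1787 for day 18, 267 for day 36 and 6341 for the interaction. In shoot the detection share gave 2 for day 11, 0 for day 15, 0 for day 22, 0 for day 29 and 1 for the interaction, and 6114 for the nitrate-by-tissue contrast. Session with detection share gave root counts of 721 for the averaged effect, 1343 for day 11, 5409 for day 18, 1 for day 22, 188 for day 32, 83 for day 36 against day 11 and 9992 for the interaction. In shoot session with detection share gave 83 for the averaged effect, 0 for day 11, 0 for day 15, 0 for day 22, 0 for day 29 and 2 for the interaction, and 446 for the nitrate-by-tissue contrast. The position as a fixed block gave root counts of 10581 for day 11, 0 for day 15, 174 for day 18, 1 for day 22, 1699 for day 29, 29 for day 32, 7 for day 36 and 8082 for the interaction. In shoot the position as a fixed block gave 6935 for the averaged effect, 2 for day 11, 0 for day 29 and 3951 for the interaction. Taking off each array's GC trend gave root counts of 1030 for day 18 and 68 for day 36. In shoot taking off each array's GC trend gave 5313 for the averaged effect, 6559 for day 11, 8425 for day 18, 0 for day 22, 20 for day 29 and 4142 for the interaction, and 1568 for the nitrate-by-tissue contrast. Where a count was 0, limma gave between 1873 and 8060 probes at an unadjusted p below 0.05 for the shoot averaged effect, 1058 and 7735 for shoot day 11, 329 and 9772 for day 15, 3251 and 5997 for day 18, 1101 and 4374 for day 22, 1451 and 6393 for day 29, 326 and 1917 for day 32, 352 and 4015 for day 36 and 1882 and 5808 for the shoot interaction. In root the zero counts had 1109 for the averaged effect, 1097 for day 15 and 1220 to 3661 for day 36.

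Leaving out single arrays moved these counts or ended these calls, and the cause was not tested. Root day 15 ranged from 8 to 91 and moved without 0.5 mM replicate 1 (8), 0.5 mM replicate 2 (30), 2.5 mM replicate 1 (33), 2.5 mM replicate 2 (17) and 2.5 mM replicate 3 (47). Root day 18 ranged from 174 to 6292 and moved without 0.5 mM replicate 1 (174), 0.5 mM replicate 3 (350), 2.5 mM replicate 1 (6292), 2.5 mM replicate 2 (673) and 2.5 mM replicate 3 (201). Root day 22 ranged from 1 to 2 and moved without 0.5 mM replicate 1 (1), 0.5 mM replicate 2 (1), 0.5 mM replicate 3 (1), 2.5 mM replicate 2 (1) and 2.5 mM replicate 3 (1). Root day 29 ranged from 2448 to 10699 and moved without 0.5 mM replicate 1 (2448), 0.5 mM replicate 2 (10699), 0.5 mM replicate 3 (4002), 2.5 mM replicate 1 (3746) and 2.5 mM replicate 3 (3209). Root day 32 ranged from 17 to 903 and moved without 0.5 mM replicate 1 (23), 0.5 mM replicate 3 (903), 2.5 mM replicate 1 (17), 2.5 mM replicate 2 (29) and 2.5 mM replicate 3 (23). Root day 36 ranged from 0 to 2592 and moved without 0.5 mM replicate 1 (2592), 0.5 mM replicate 2 (2), 0.5 mM replicate 3 (0), 2.5 mM replicate 1 (0), 2.5 mM replicate 2 (3) and 2.5 mM replicate 3 (17). Shoot day 11 ranged from 4984 to 9861 and moved without 0.5 mM replicate 3 (4984), 2.5 mM replicate 1 (5586) and 2.5 mM replicate 2 (7966). Shoot averaged effect ranged from 7261 to 13195 and moved without day 15 0.5 mM replicate 1 (7261). Shoot day 15 ranged from 0 to 1 and moved without 0.5 mM replicate 1 (0), 2.5 mM replicate 1 (0), 2.5 mM replicate 2 (0) and 2.5 mM replicate 3 (0). Shoot day 18 ranged from 7748 to 14230 and moved without 2.5 mM replicate 3 (7748). Shoot day 22 ranged from 0 to 20 and moved without 0.5 mM replicate 1 (0), 0.5 mM replicate 2 (20), 0.5 mM replicate 3 (10), 2.5 mM replicate 2 (0) and 2.5 mM replicate 3 (0). Shoot day 29 ranged from 0 to 729 and moved without 0.5 mM replicate 1 (0), 0.5 mM replicate 2 (0), 0.5 mM replicate 3 (729), 2.5 mM replicate 1 (1), 2.5 mM replicate 2 (18) and 2.5 mM replicate 3 (0). Shoot day 32 ranged from 0 to 1 and moved without 0.5 mM replicate 3 (1). The nitrate-by-tissue count ranged from 1185 to 4794 and moved without 29 arrays. These were in root day 11 0.5 mM replicate 3 (3948), day 11 2.5 mM replicate 1 (1627), day 11 2.5 mM replicate 3 (4190), day 15 0.5 mM replicate 3 (1517), day 15 2.5 mM replicate 3 (1545), day 18 0.5 mM replicate 2 (1663), day 29 0.5 mM replicate 1 (1652), day 32 0.5 mM replicate 1 (4401), day 32 0.5 mM replicate 3 (1454) and day 36 0.5 mM replicate 1 (1666). They were in shoot day 15 0.5 mM replicate 1 (1185), day 15 0.5 mM replicate 2 (4419), day 15 0.5 mM replicate 3 (3991), day 18 2.5 mM replicate 3 (1282), day 22 0.5 mM replicate 1 (3990), day 22 0.5 mM replicate 3 (1468), day 22 2.5 mM replicate 1 (1608), day 22 2.5 mM replicate 2 (4044), day 29 0.5 mM replicate 1 (1534), day 29 0.5 mM replicate 2 (1542), day 29 0.5 mM replicate 3 (4794), day 29 2.5 mM replicate 3 (1510), day 32 0.5 mM replicate 1 (4102), day 32 0.5 mM replicate 3 (1227), day 32 2.5 mM replicate 1 (4283), day 32 2.5 mM replicate 2 (1391), day 36 0.5 mM replicate 1 (1239), day 36 0.5 mM replicate 2 (4140) and day 36 0.5 mM replicate 3 (4118). P1000248044 in root on day 11 lost its call without 0.5 mM replicate 1 (2.93). P1000312260 in root on day 15 lost its call without 0.5 mM replicate 1 (3.05), 2.5 mM replicate 1 (2.33) and 2.5 mM replicate 2 (3.26). P1000266653 in root on day 15 lost its call without 0.5 mM replicate 1 (-3.31), 0.5 mM replicate 2 (-3.64), 2.5 mM replicate 1 (-3.47) and 2.5 mM replicate 3 (-3.45). P1000234694 in root on day 15 lost its call without 0.5 mM replicate 1 (-3.33), 0.5 mM replicate 2 (-3.23), 2.5 mM replicate 1 (-3.36), 2.5 mM replicate 2 (-3.67) and 2.5 mM replicate 3 (-3.59). P1000288064 in root on day 18 lost its call without 0.5 mM replicate 1 (3.62), 0.5 mM replicate 2 (3.56) and 2.5 mM replicate 3 (3.03). P1000289193 in root on day 18 lost its call without 0.5 mM replicate 1 (-3.75), 0.5 mM replicate 3 (-4.43), 2.5 mM replicate 1 (-2.77) and 2.5 mM replicate 3 (-3.54). P1000289149 in root on day 22 lost its call without 0.5 mM replicate 1 (1.29), 0.5 mM replicate 2 (1.31), 0.5 mM replicate 3 (1.31), 2.5 mM replicate 2 (1.24) and 2.5 mM replicate 3 (1.09). P1000217375 in root on day 22 lost its call without 0.5 mM replicate 1 (-1.79), 0.5 mM replicate 2 (-1.53), 0.5 mM replicate 3 (-1.88), 2.5 mM replicate 1 (-1.72), 2.5 mM replicate 2 (-1.70) and 2.5 mM replicate 3 (-1.79). P1000269778 in root on day 32 lost its call without 0.5 mM replicate 1 (2.93), 0.5 mM replicate 3 (2.03), 2.5 mM replicate 1 (2.89), 2.5 mM replicate 2 (2.32) and 2.5 mM replicate 3 (3.02). P1000243952 in root on day 32 lost its call without 0.5 mM replicate 1 (-1.28), 0.5 mM replicate 2 (-1.48), 2.5 mM replicate 1 (-1.38) and 2.5 mM replicate 2 (-1.37). P1000286390 in root on day 32 lost its call without 0.5 mM replicate 1 (-1.13) and 2.5 mM replicate 3 (-1.14). P1000303818 in root on day 32 lost its call without 2.5 mM replicate 2 (2.79). P1000219531 in root on day 36 lost its call without 0.5 mM replicate 2 (3.42), 0.5 mM replicate 3 (3.54), 2.5 mM replicate 1 (3.43) and 2.5 mM replicate 2 (3.54). P1000235506 in root on day 36 lost its call without 0.5 mM replicate 2 (3.37), 0.5 mM replicate 3 (3.69), 2.5 mM replicate 1 (3.53) and 2.5 mM replicate 2 (3.40). P1000256434 in root on day 36 lost its call without 0.5 mM replicate 2 (-1.82), 0.5 mM replicate 3 (-2.10), 2.5 mM replicate 1 (-1.97), 2.5 mM replicate 2 (-1.97) and 2.5 mM replicate 3 (-1.93). P1000238913 in root on day 36 lost its call without 0.5 mM replicate 2 (-1.86), 0.5 mM replicate 3 (-1.53), 2.5 mM replicate 1 (-1.83), 2.5 mM replicate 2 (-1.92) and 2.5 mM replicate 3 (-2.10). P1000270020 in shoot on day 11 lost its call without 2.5 mM replicate 2 (-3.55). P1000269315 in shoot on day 15 lost its call without 0.5 mM replicate 1 (2.75), 0.5 mM replicate 3 (2.63), 2.5 mM replicate 1 (2.77), 2.5 mM replicate 2 (2.79) and 2.5 mM replicate 3 (3.07). P1000310302 in shoot on day 18 lost its call without 0.5 mM replicate 1 (5.82), 0.5 mM replicate 2 (5.90), 0.5 mM replicate 3 (5.86), 2.5 mM replicate 1 (4.80) and 2.5 mM replicate 3 (4.25). P1000227203 in shoot on day 22 lost its call without 0.5 mM replicate 1 (-1.99), 2.5 mM replicate 2 (-2.00) and 2.5 mM replicate 3 (-2.25). P1000303685 in shoot on day 29 lost its call without 0.5 mM replicate 1 (1.14), 0.5 mM replicate 2 (1.20), 2.5 mM replicate 1 (1.26) and 2.5 mM replicate 3 (1.12). P1000258600 in shoot on day 29 lost its call without 0.5 mM replicate 1 (-2.94), 0.5 mM replicate 2 (-2.45), 2.5 mM replicate 1 (-3.01), 2.5 mM replicate 2 (-2.67) and 2.5 mM replicate 3 (-2.80). P1000302207 in shoot on day 29 lost its call without 0.5 mM replicate 1 (-1.93), 0.5 mM replicate 2 (-1.75), 2.5 mM replicate 1 (-2.08) and 2.5 mM replicate 3 (-1.72).

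The scaling changed the share of called probes that were higher at 0.5 mM, or higher in root. For root day 11 it was 29.9%, and 45.4% with normexp, 48.7% with quantile normalization and 54.2% without the GC trend. For root day 29 it was 42.7%, and 54.8% with quantile normalization and 59.2% without the GC trend. For root day 32 it was 96.6%, and 86% without the GC trend, and for root day 36 62.2%, and 26.5% without it. For the shoot averaged effect it was 58.8%, and 39.6% with normexp. For shoot day 11 it was 70%, and 48.2% without the GC trend, and for shoot day 18 70.7%, and 47% with quantile normalization and 59.6% without the GC trend. For the tissue contrast it was 49%, and 36.1% with normexp, and for the nitrate-by-tissue contrast 38.6%, and 67.4% with normexp and 56.8% without the GC trend. The median log2 difference over all probes moved by over 0.1 in these cases. With normexp it went in root to 0.15 on day 22 from -0.00227, 0.403 on day 32 from 0.0675, -0.368 on day 36 from 0.065 and 0.257 for day 36 against day 11 from 0.072. In shoot it went to 0.0825 on day 11 from 0.195, -0.401 on day 15 from 0.0312, 0.773 on day 18 from 0.136, -0.359 on day 32 from -0.0978, 0.623 on day 36 from 0.0617 and 0.172 for day 36 against day 11 from -0.0915, and for the tissue contrast to -0.412 from -0.0394. Quantile normalization and the GC trend brought it to between -0.0819 and 0.0205 on root days 11, 18 and 29 (from -0.317, 0.105 and -0.143), on shoot days 11, 18, 22 and 29 (from 0.195, 0.136, -0.127 and -0.184) and for shoot day 36 against day 11 (from -0.0915), by the GC trend alone for shoot day 22 and day 36 against day 11.

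No paired analysis was possible because the labels give no replicate numbers that link arrays of different groups. The planned tests of gene lists, with either correlation, and the choice of a probe per gene were not run, since no list had a member on the array. The 7 against 7 test of the deposited series values had a lowest adjusted p of 0.419 in root and 0.111 in shoot.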

Other observations

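Tests chosen only after the result was seen were those of a deviating array, of the spread inside groups and of the array position on day 29, and the overlaps with the day 29 set of 2406 probes. The deviating-array test was reworded then to ask for exactly 1 such array, and under its first wording, any array that brought the count under 50% of the one reported, it would have favoured that explanation.

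Root probes that differed with nitrate overlapped with those that changed over the life cycle. Of the 728 probes lower at 0.5 mM on average, 417 were higher on day 36 than on day 11, where independent lists would share 219.6, and of the 683 higher at 0.5 mM, 249 were lower on day 36, against 162.3. In the day 29 set, 849 of the 1235 probes lower at 0.5 mM were higher on day 36 than on day 11, against 372.5, and 464 of the 1171 higher ones were lower on day 36, against 278.3. Of the 1171, 709 were higher in root than in leaf blade, against 528.3, and of the 1235, 651 were, against 557.2. These overlaps were not tested, and lists taken from the same arrays are not independent.

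In the leaf blade, 1895 of the 4526 probes lower at 0.5 mM on average were also lower on day 36 than on day 11, where independent lists would share 1264, and 621 of the 6456 higher ones were lower on day 36, against 1803. Of the probes higher on day 36 in the leaf blade, 5560 were higher in root than in leaf blade, against 3445. There were 25417 probes above background on all 84 arrays and 1368 on none.

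The third pattern weighed was the root effect of day 29 with 6601 probes. Spread inside groups stays open, as the 2 axes come from the same probes. With them 5265 passed (3741 of the 6601 with the same sign), and with the control-probe pattern 3980 (2456). A deviating array stays open, because the count was 2448 without replicate 1 at 0.5 mM and 3209 without replicate 3 at 2.5 mM, and so does the array position, because 1699 passed with it as a block and all 3 arrays at 0.5 mM lay in position 3 while 2 of those at 2.5 mM lay in position 4. Plants at 0.5 mM that were at another stage cannot be told apart from a nitrate response, since r across probes with the change from days 18 and 22 to days 32 and 36 was -0.169 with the control-probe pattern, 0.113 without a covariate, -0.19 with 2 array axes and -0.588 with the session, while over the 2406 probes of the set it was -0.59, -0.548, -0.604 and -0.658. Each of these may contribute, and a nitrate response stays open, as untested.

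Chance can be excluded for root change over days (29267 probes, highest of the other splits 1603), shoot change over days (31080 and 625), root day 36 against day 11 (19903 and 18285), shoot day 36 against day 11 (18400 and 14618) and root against shoot (33982 and 14834), each with 1 of 100 splits as large, the real one. For single days the 10 splits of 6 arrays are too few for a share under 0.05. In root the real count and the highest other were 20376 and 9935 on day 11, 91 and 0 on day 15, 3388 and 3 on day 18, 3 and 0 on day 22, 6601 and 0 on day 29, 58 and 4418 on day 32, and 37 and 7689 on day 36. In shoot they were 11990 and 2 on day 11, 1 and 1 on day 15, 14335 and 1 on day 18, 1 and 2 on day 22, 4 and 6 on day 29, 0 and 0 on day 32, and 0 and 5614 on day 36, where limma gave 1116 and 805 probes at an unadjusted p below 0.05 for the real split of days 32 and 36. On root days 32 and 36 and shoot day 36 another split called many more probes than the real one, which points to a structure of the samples.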
